A study of Homo sapiens with 6 samples.

How the data were processed

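Total RNA from 3 non-small cell lung cancer (NSCLC) lines was hybridised to Agilent human microarrays with a single dye, Cy3, per the labels' protocols. Each line gave 1 array after an siRNA named NC and 1 array after an siRNA against ETV4, both taken at 48 h, so that 6 arrays were used. The deposited files hold spot intensity values on a linear scale, per the file headers. They were made with Agilent Feature Extraction 11.0.1.1 under its protocol for single-colour gene expression, with background subtraction and spatial detrending and no scaling between arrays, per the file headers. The array design was number 079487. All 6 arrays belonged to 1 scan, per the file headers, and the position codes put the 3 NC siRNA arrays and the H358T ETV4 siRNA array in the same row of the slide and the other ETV4 siRNA arrays in another.

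The processed intensity of each spot was set to log2, each array's 75th percentile over non-control probes was subtracted, and the spots of each probe were averaged. The 1439 control spots and 60 probes whose names mark them as negative controls were left out, as were spots marked as outliers, which removed 146 probes. Outlier spots numbered 112 on the H1703 ETV4 siRNA array and 9 to 18 on each of the others. No spot was saturated. A probe was tested when its signal was well above background, as the scanner software marks it, on at least 2 of the 6 arrays, which kept 43180 probes. The mean processed signal per array ran from 2060 to 4016, and 62.0% to 68.8% of probes were well above background. The number of arrays limits the precision. The 20 probes spotted 10 times each had a median SD between spots of 0.05 to 0.10 log2 units within an array.

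Gene names came from the files and from a table of RefSeq genes (assembly GRCh38.p14), used for names alone. The files give 20 of the 60924 probes a RefSeq accession, and 20 of those 20 matched a gene symbol; the other 60904 carry only a design identifier that neither source pairs with a gene. Tests were therefore made per probe and not per gene, as had been planned. The level of ETV4, the other genes chosen beforehand (ETV1, ETV5, PXN and MMP1) and the pathway and cell type lists fixed beforehand were not analysed here, since a list needed 5 named members and none had more than 2. Probes for GAPDH, ACTB, ACTG1, RPL10, RPLP1, RPS18 and H3-3A may also bind transcripts of near-identical paralogs or pseudogenes, and their values are uncertain in that respect.

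ETV4 siRNA was compared with NC siRNA using limma 3.58.1 in R 4.3.3, with lmFit and eBayes, the cell line as a block and the Benjamini-Hochberg adjustment over all probes tested, at a threshold of 0.05. The signal given for a probe in a group is a geometric mean over its arrays. Values are mean log2 differences, ETV4 siRNA minus NC siRNA, with the SD over the 3 lines. The lines pair the arrays: arrays of a line deviated together from their group means, with correlations across probes of 0.89 in H358T, 0.83 in H1299 and 0.79 in H1703. The labels do not speak of repeated cultures, so each p-value for the siRNA comparison measures only the spread between these 3 lines. Within a line there was 1 array per siRNA and no test, and probes were counted by a log2 difference of at least 1 in size, if well above background on at least 1 of the line's arrays. Overlaps between lines were set against the count expected of independent lists. An exact sign-flip permutation test over 3 lines (two-sided) cannot give a p below 0.25 and was not used for calls. A probe not well above background on any array of a group was given a lower bound of its fold, against the lowest signal among probes well above background on each of those arrays.

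Text names were chosen by a rule set before the data were examined: the genes above, and the probes with the same sign in all 3 lines and the largest value of their smallest difference, of which 2 in each direction are given by identifier because they have no gene name. The named genes are reported in addition and were chosen because the files name them; some of them were tested with the rest but are not reported here. Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, centring on the median of detected probes, no filter, a filter of all 6 arrays, no block, eBayes with trend and robust settings, other thresholds, and leaving out each line. Normexp was run on median spot signals, since the mean signal it was planned for is not among the columns used here. A term for array row and the addition of GAPDH and PGK1 control spots to the fit were chosen after the data were seen.

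The fit was tested on simulated data of 43180 probes with the spread of the real fit. In 5 runs with 200 changed probes each, limma recovered 0.4% of the 2-fold and 59.2% of the 4-fold changes, with 24 false calls among 322. With 20% of probes changed, it recovered 78.5% of the 2-fold and 98.4% of the 4-fold changes, and 4.07% of calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.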

Results

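Gene expression was profiled in 3 NSCLC cell lines 48 h after transfection with an siRNA against ETV4, an ETS-family transcription factor, or with an siRNA named NC. H1299 and H1703 are established NSCLC lines, and H358T denotes H358 cells treated with TGF-β. Each line contributed 1 array per siRNA, which gave 3 arrays for each siRNA. The mean processed signal was between 2060 and 2237 on all arrays except that of H1703 with ETV4 siRNA, where it was 4016. Of the 60924 probes, 20 could be assigned to a gene from the files, and genes from among these are described by symbol. The silencing of ETV4 was not analysed here, because none of these 20 probes reports it, so the labels of the siRNA groups could not be checked on their target.

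The first comparison addressed which transcripts responded to ETV4 siRNA across the 3 lines. ETV4 siRNA changed 614 of 43180 probes in limma (Benjamini-Hochberg adjusted p threshold 0.05), of which 373 rose and 241 fell. All 614 had the same sign in each of the 3 lines and a mean difference of at least 2-fold, with a median size of 1.46 on the log2 scale, and 72 differed at least 4-fold. The calls were made on these same 3 differences, so the shared sign and large size are not separate evidence. Probe ASHGV40047229 rose 7.73-fold, with a mean log2 difference of 2.95 ± 0.23 (SD, n = 3 lines; limma adjusted p = 0.0386), and its log2 differences were 3.19 in H358T, 2.92 in H1299 and 2.74 in H1703. Probe ASHGV40032321 rose 8.73-fold (log2 3.13 ± 0.93, SD, n = 3 lines; limma adjusted p = 0.0386), with 4.20 in H1703 against 2.64 in H358T and 2.54 in H1299. The steepest fall among the probes chosen was that of ASHGV40020386, 13.9-fold (log2 -3.79 ± 0.98, SD, n = 3 lines; limma adjusted p = 0.0386), from a mean signal of 775 with NC siRNA. With normexp background correction the mean log2 difference of ASHGV40020386 was -2.78 and that of ASHGV40047229 was 2.09, and both still passed in limma (adjusted p = 0.0356 and 0.0385). ASHGV40050666 was at least 2.39-fold lower (limma adjusted p = 0.0386), since it was well above background on the 3 NC siRNA arrays and on 0 of the ETV4 siRNA arrays, and its call was lost with normexp background correction (limma adjusted p = 0.0903). The files and the reference table pair none of these 4 probes with a gene.

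Among all probes tested, 10581 were higher and 8205 lower in each of the 3 lines, which is 43.5% against 25% for signs drawn at random. Quantile normalization gave 490 higher and 417 lower probes in limma, 592 of them shared with the 614, whereas normexp called 898 probes and shared 364, and requiring signal on all 6 arrays called 2079 and shared 459. The limma fit called 0 probes without the cell line as a block (2001 at an unadjusted p under 0.05), 0 with any 1 line left out (6350 to 8085) and 0 without the filter on dim probes (9453). With array row as a term it also called 0 (3891 at an unadjusted p under 0.05), a fit in which H358T, whose arrays share a row, alone sets the siRNA effect.

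The same comparison was read out for the 20 named genes, none of which passed the threshold in limma over all probes. ARHGDIA came nearest, with a mean log2 difference of -0.87 ± 0.23 (SD, n = 3 lines), a 1.82-fold lower level (limma adjusted p = 0.0742, and 0.0570 when adjusted over the 20 genes). It was lower in each line, by log2 differences of -0.61 in H358T, -1.06 in H1299 and -0.93 in H1703, and passed the threshold in limma under quantile normalization (-1.19 ± 0.32; adjusted p = 0.0472). The glutamate receptor gene GRM4 had a mean difference of -0.74 ± 0.49 (limma adjusted p = 0.149) at a low signal of 46.4 with NC siRNA, and of -0.28 with normexp background correction. For the glycolytic enzyme gene GAPDH the mean difference was -0.65 ± 0.28 (limma adjusted p = 0.131), and -1.11 ± 0.51 after quantile normalization. Control spots for GAPDH on the array had mean differences from -0.42 (Mouse-GAPDH_5, limma adjusted p = 0.225 with these spots in the fit) to -2.39 (Rat-GAPDH_5, limma adjusted p = 0.0383). Human-GAPDH_5 had -2.01 ± 0.49 (SD, n = 3 lines, limma adjusted p = 0.0383), and Human-GAPDH_3 had -1.01 ± 0.21 (limma adjusted p = 0.0559). The RNA was human, and how far the mouse and rat spots report human GAPDH was not tested. The outer mitochondrial membrane gene MTX1 (-0.36 ± 0.32) and the arginine methyltransferase gene PRMT1 (-0.26 ± 0.41) had smaller mean differences, which quantile normalization moved to -0.62 ± 0.34 and -0.76 ± 0.39.

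**Figure D1:**
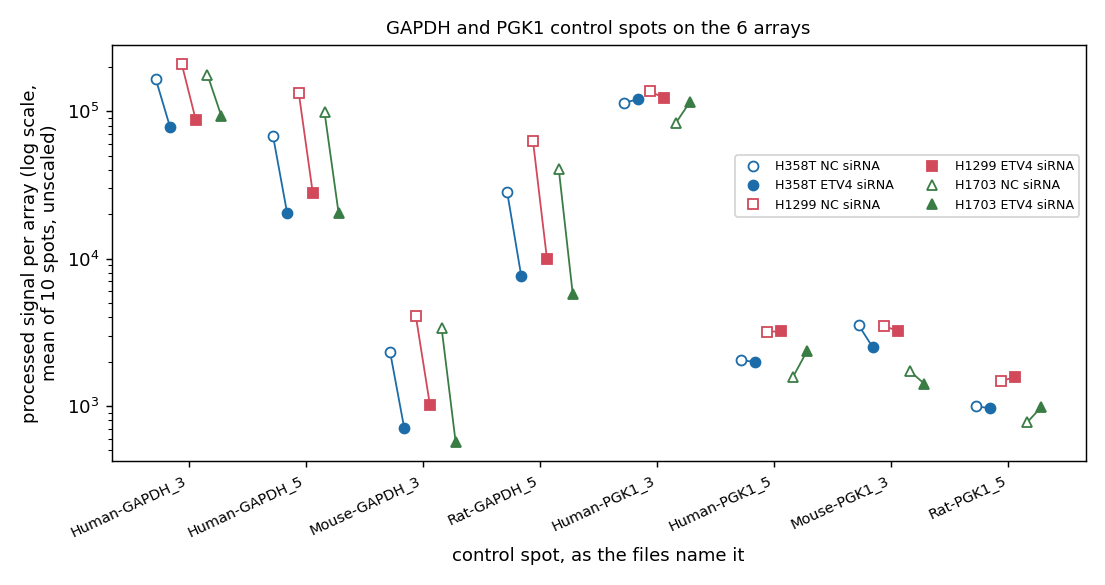
Processed signal (y axis, log scale, unscaled mean of 10 spots) of GAPDH and PGK1 control spots (x axis, named as in the files) on the 6 arrays, with lines joining NC siRNA (open) to ETV4 siRNA (filled) in each cell line. Human-GAPDH_5 has a geometric mean of 96492 with NC siRNA and of 22672 with ETV4 siRNA.

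The highest mean difference of a named gene was that of EIF3D, a subunit of translation initiation factor eIF3, with 0.74 ± 0.52 (SD, n = 3 lines; limma adjusted p = 0.163). It was higher in each line under both scalings, although quantile normalization lowered its mean to 0.27 ± 0.09. The actin genes ACTB (0.21 ± 0.46) and ACTG1 (0.19 ± 0.38), the actin-binding profilin gene PFN1 (0.12 ± 0.56) and the dynein light chain gene DYNLL1 (0.33 ± 0.23) had means above 0 that turned negative after quantile normalization. This was also so for RPLP1 (0.36 ± 0.33), RPS18 (0.21 ± 0.26) and RACK1 (0.26 ± 0.34), whose products belong to the ribosome, for the cytochrome c oxidase subunit gene COX4I1 (0.36 ± 0.38), for the ornithine decarboxylase gene ODC1 (0.09 ± 0.31) and for the glycolytic gene PGK1 (0.04 ± 0.32). RPL10 was nearest to 0 of the 20, at -0.04 ± 0.15, and the histone gene H3-3A had 0.45 ± 0.36, which became 0.02 ± 0.53 with quantile normalization. Of the gene lists fixed beforehand, hypoxia and glycolysis held 2 named members, GAPDH and PGK1, and ribosomal proteins held 2, RPL10 and RPLP1, short of the 5 needed for a test.

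**Figure D2:**
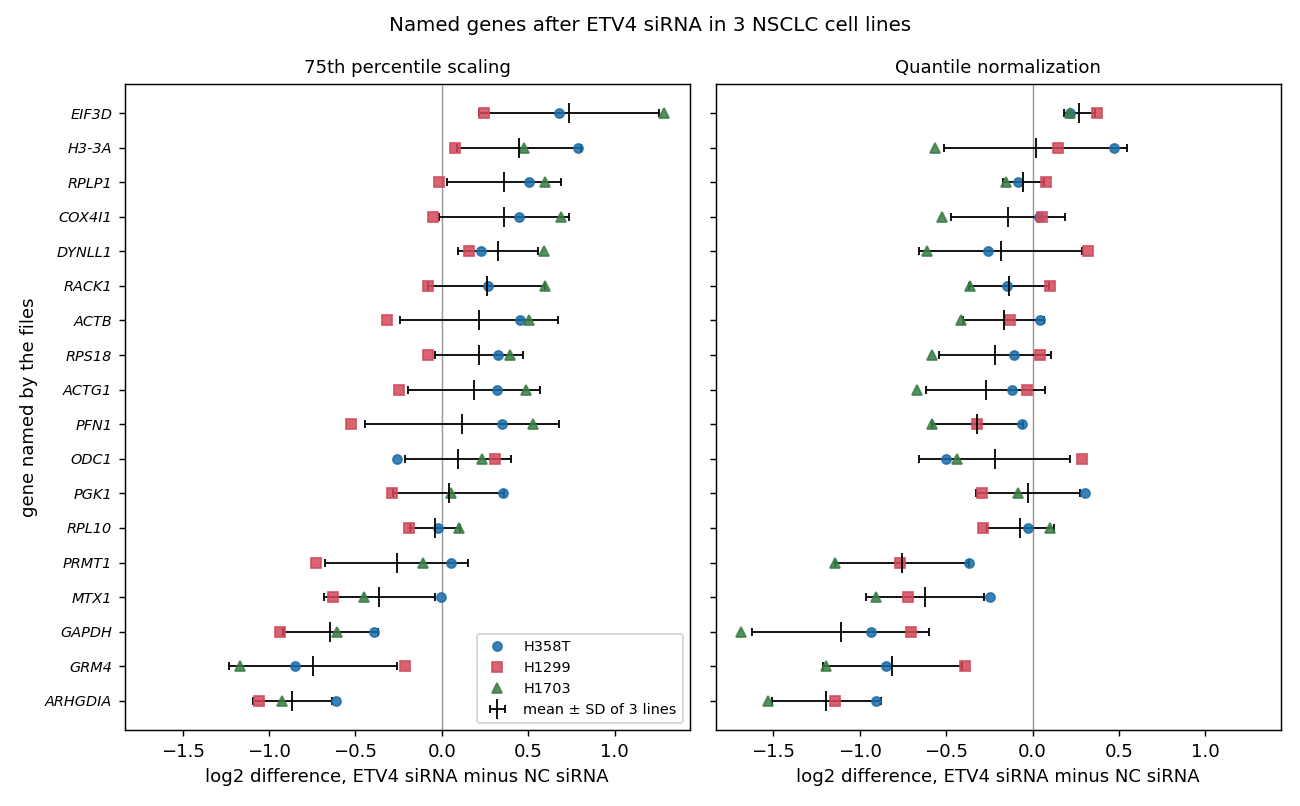
Log2 difference between ETV4 siRNA and NC siRNA (x axis) of the genes reported by symbol (y axis), per line (points) and as mean ± SD of the 3 lines (bars), with 75th percentile scaling on the left and quantile normalization on the right. ARHGDIA, GRM4 and GAPDH lie below 0 in each line in both panels, EIF3D lies above it, and MTX1 lies below it but at -0.0051 in H358T in the left panel.

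The second comparison described the response within each line, where 1 array per siRNA allowed counts by size but no test. Of the named genes, GRM4 (-1.17) and EIF3D (1.29) differed at least 2-fold in H1703 and ARHGDIA (-1.06) in H1299, and no named gene did in H358T. After quantile normalization EIF3D in H1703 was at 0.22, GRM4 in H1703 and ARHGDIA in H1299 stayed past 2-fold (-1.20 and -1.14), and ARHGDIA (-1.53), GAPDH (-1.69) and PRMT1 (-1.14) also passed it in H1703. In H358T, 1978 probes were at least 2-fold higher and 1307 at least 2-fold lower with ETV4 siRNA, which is 7.85% of 41837 probes. H1299 had 2141 higher and 1874 lower, 9.26% of 43377, and H1703 had 3111 higher and 1808 lower, 12.3% of 40103. Higher probes made up 60.2% of those counted in H358T, 53.3% in H1299 and 63.2% in H1703. After quantile normalization the shares were 57.9%, 45.8% and 52.7%, so that the direction of the excess turned in H1299. It turned there too with normexp (626 higher and 877 lower) and with signal required on all 6 arrays (1076 and 1232). Normexp also lowered the counts to 585 higher and 390 lower in H358T and to 1789 and 522 in H1703. The H1703 array with ETV4 siRNA was brighter at its upper end: in the brightest decile of probes, the median log2 difference was 0.46 in H1703, 0.22 in H358T and 0.01 in H1299.

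**Figure D3:**
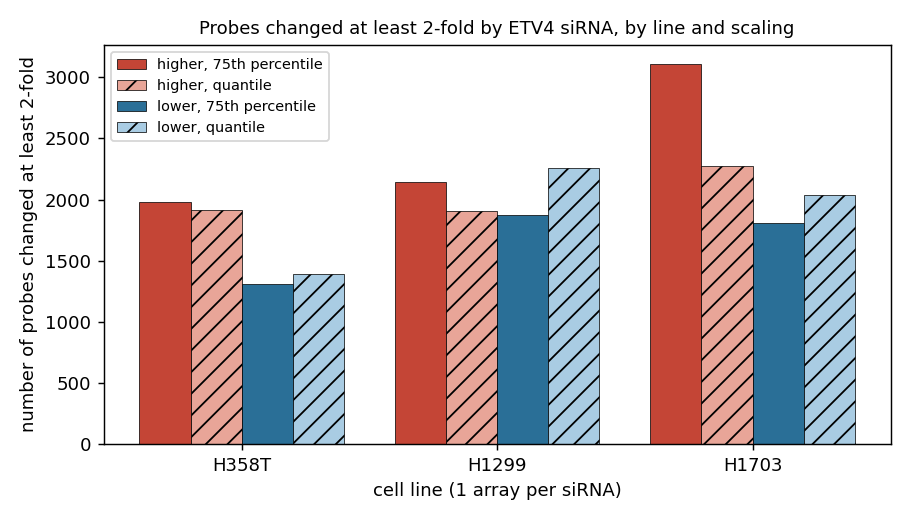
Number of probes (y axis) at least 2-fold higher or lower with ETV4 siRNA in each cell line (x axis), after 75th percentile scaling (solid) and quantile normalization (hatched), from 1 array per siRNA. The higher probes of H1703 number 3111 with the first scaling and 2276 with the second.

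**Figure D4:**
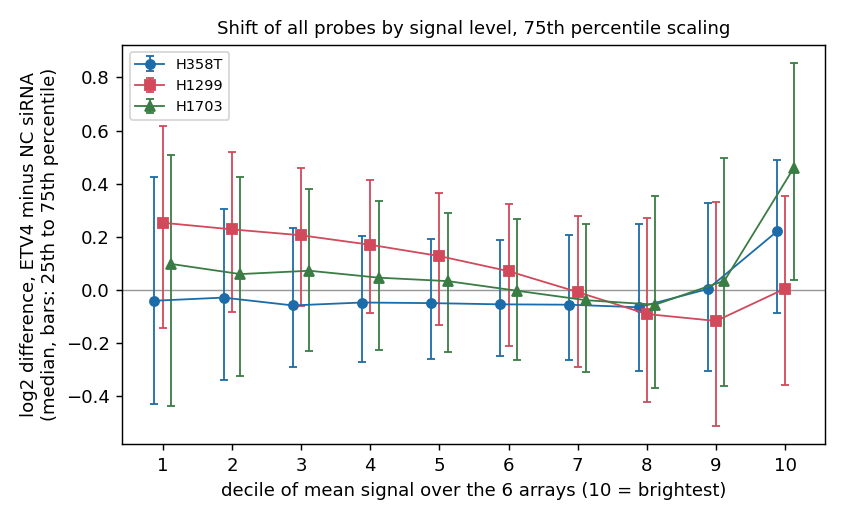
Median log2 difference between ETV4 siRNA and NC siRNA (y axis; bars, 25th to 75th percentile of probes) by decile of mean signal over the 6 arrays (x axis), for each line after 75th percentile scaling. The brightest decile of H1703 lies at 0.46, above those of H358T at 0.22 and H1299 at 0.01.

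The third comparison addressed how far the 3 lines shared their response. ARHGDIA, GRM4 and GAPDH were lower and EIF3D higher in each line, while ACTB differed in sign, with 0.45 in H358T, 0.50 in H1703 and -0.32 in H1299, values that became 0.04, -0.42 and -0.13 after quantile normalization. PFN1 had -0.52 in H1299 against 0.35 in H358T and 0.53 in H1703, although quantile normalization put it below 0 in each line. Of 37805 probes measured in every line, 304 were at least 2-fold higher in all 3 and 214 at least 2-fold lower in all 3, and 38 passed 2-fold in all 3 with mixed signs. The same direction thus held for 93.2% of the probes past 2-fold in every line, against 25% for random signs. It held for 29.3% in simulated lines that had no response and varied independently. Independent lists would share 3.13 higher and 1.20 lower probes. However, the simulated lines without a response shared 50.7 times as many higher probes as independent lists would, because probes differ in spread. The spread of each simulated probe was drawn without regard to its signal.

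Taken in pairs, jointly 2-fold probes had the same direction in 92.4% of cases for H1299 and H1703, 94.3% for H358T and H1703 and 91.9% for H358T and H1299. This compares with 50% by chance and 51.0% in simulated lines that had no response and varied independently. Between H1299 and H1703, 743 probes were higher and 589 lower in both, 6.89 and 10.3 times the count of independent lists, and 110 were opposite. H358T shared 608 higher and 349 lower probes with H1703 (6.40 and 10.0 times; 58 opposite) and 481 higher and 343 lower with H1299 (8.16 and 8.28 times; 73 opposite). The simulated lines without a response shared 5.12 times the count of independent lists. Across 43180 probes, which are not independent replicates, the log2 differences correlated with Pearson r = 0.39 and a Spearman coefficient of 0.42 between H1299 and H1703, 0.39 and 0.38 between H358T and H1703, and 0.36 and 0.33 between H358T and H1299.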

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

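The tests of explanations in this part were chosen only after the results were seen.

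Of the control spots for the glycolytic gene GAPDH, which the comparisons of probes leave out, Human-GAPDH_5 (log2 -2.01 ± 0.49, SD, n = 3 lines), Rat-GAPDH_5 (-2.39) and Mouse-GAPDH_3 (-2.02) fell with ETV4 siRNA (limma adjusted p = 0.0383, 0.0383 and 0.0418 with these spots in the fit), whereas Human-GAPDH_3 (-1.01; 0.0559), Rat-GAPDH_3 (-0.98; 0.0936) and Mouse-GAPDH_5 (-0.42; 0.225) were lower without passing, and Human-PGK1_5 had 0.26 ± 0.22. For Human-GAPDH_5, array scaling and compression of bright signals are argued against, because it stood at -2.37 ± 0.61 after quantile normalization, beyond the -1.19 of ARHGDIA, the lowest of the other 19 named genes. An effect of array row as the whole cause is argued against by the -1.45 in H358T, whose arrays share a row. Those arrays lie at different positions along it, and an effect of that position was not tested. The falls were larger in H1299 (-2.22) and H1703 (-2.36), whose arrays lie in different rows, so a partial effect of array row stays open. It remains open whether the reagent acted on GAPDH mRNA directly, as an siRNA against GAPDH under the ETV4 label would. Such an action could not be checked without a value for ETV4 and would change what every difference here means. Also open is whether GAPDH mRNA was lowered through ETV4 or through another effect of the siRNA, neither of which was tested. The named GAPDH probe had a smaller difference, -0.65 ± 0.28 (limma adjusted p = 0.131), and -1.11 ± 0.51 after quantile normalization. This does not decide the question, because its signal with NC siRNA (263162) was above that of either human control spot and compression could have lessened its difference. The difference of human spot 5 minus that of spot 3 was -0.999 ± 0.33 for GAPDH and 0.06 ± 0.15 for PGK1. The rat GAPDH spots ran the same way (-2.39 for spot 5 and -0.98 for spot 3). The mouse GAPDH spots ran the other way (-0.42 and -2.02). Both of these pairs hold a dim spot, and how far they report human GAPDH was not tested. With NC siRNA, Mouse-GAPDH_5 had a signal of 135, against 3164 for Mouse-GAPDH_3. Rat-GAPDH_3 was dimmer still, against 41614 for Rat-GAPDH_5. The gap between the human spots does not decide the question either. Compression of the brighter human spot 3 (183248 against 96492 with NC siRNA) could give such a gap, and the files do not say what 3 and 5 denote.

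The number of probes at least 2-fold higher was larger in H1703 (3111) than in H358T (1978) or H1299 (2141), a pattern noticed in the counts per line. A stretched bright end of the H1703 array with ETV4 siRNA may account for part of the excess: under quantile normalization the share of higher probes in H1703 became 52.7%, between the 45.8% of H1299 and the 57.9% of H358T. Normexp (1789 higher and 522 lower) and signal required on all 6 arrays (2316 and 985) kept the excess of higher probes in H1703, but neither rescales the bright end of an array. A larger response of H1703 stays open as well, since this line kept the highest total after quantile normalization, 4316 probes against 4168 in H1299 and 3311 in H358T. With 1 array per siRNA in each line, the spread needed to settle that was not measured. The arrays of H358T share a row of the slide, while those of H1299 and of H1703 lie in different rows. The lower counts of H358T therefore cannot be told apart from an effect of array row.

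Many of the same probes changed in all 3 lines. An effect of array row as the whole cause is argued against by H358T, whose arrays share a row and whose differences still correlated at 0.36 or more with those of the other lines; an effect of position along the row was not tested. The 6 arrays make 10 splits, too few for a share under 0.05; the real one, 1 of the 10, called 614 probes in limma, and the highest other split called 101. The lines pair the arrays, and the other 3 splits that part all 3 pairs as the real one does called 0, while both splits with 101 calls part 1 pair. An effect of the siRNA other than on ETV4 could change the same 614 probes in every line and cannot be told apart from one through ETV4, because the study has 1 ETV4 siRNA group.

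Some named genes had opposite signs in different lines, beyond the error between spots with 75th percentile scaling and with the same signs after quantile normalization; with 1 array per siRNA in each line, these differences were not tested. ODC1 had 0.30 in H1299 and -0.26 in H358T. RPL10 had 0.10 in H1703 and -0.19 in H1299, at a signal of only 118 with NC siRNA. ACTB had 0.45 in H358T and -0.32 in H1299, and after quantile normalization 0.04, which is about the error between spots, and -0.13. PGK1 had 0.35 in H358T and -0.29 in H1299.

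Other control spots also carried a signal. The spike-in spot (+)E1A_r60_a107 was above background on the 3 ETV4 siRNA arrays and on 0 of the NC siRNA arrays, and was at least 1.77-fold higher with ETV4 siRNA, at a mean signal of 18.9. The other E1A spots above background on any array did not rise alike. Their mean log2 differences were -0.16 for (+)E1A_r60_a22, 0.04 for (+)E1A_r60_a20 and 0.26 for (+)E1A_r60_n11. The negative-control probes Negative010 and Negative059 were above background on all 6 arrays, with mean signals of 371 and 128.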

How the results depend on the processing

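The fits with array row as a term and with control spots added were chosen only after the data were seen; the other alternatives were fixed before the data were examined. Alternatives with a slide block (all arrays share a scan), with several probes averaged per gene, for ETV4 and for the gene lists were not run, because the arrays or the names needed for them were missing. Across the 3 lines, the counts of 373 higher and 241 lower probes stayed within 1.5 times under median centring (306 and 196) and with control spots added (397 and 263). The lower probes numbered 362 with normexp, beside 536 higher, and 417 with quantile normalization, beside 490 higher. Requiring signal on all 6 arrays gave 1264 higher and 815 lower, trend and robust settings 1914 and 1318, and an adjusted p under 0.1 gave 1802 and 1120. In limma, 0 higher and 0 lower probes were called without the filter (9453 at an unadjusted p under 0.05; smallest adjusted p = 0.0925), with array row as a term (3891; smallest adjusted p = 0.359), and with each line left out (range 0 to 0; smallest adjusted p = 0.0813 to 0.165). Leaving out the replicate block that pairs the arrays of a line also gave 0 and 0 (2001 at an unadjusted p under 0.05; limma smallest adjusted p = 0.859), and the calls of the 4 probes named were lost with it; it changed no call of the 20 named genes. Without the block, differences between lines enter the error, and with a line left out fewer arrays remain. With array row as a term, H358T alone sets the siRNA effect. These limits follow from the design, but how far they account for the lost calls was not tested, nor was the cause of the other shifts.

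Within lines, normexp gave fewer probes at 2-fold: 585 higher and 390 lower in H358T, 626 and 877 in H1299, and 1789 and 522 in H1703. With signal required on all 6 arrays they were 987 and 644 in H358T, 1076 and 1232 in H1299, and 985 lower in H1703. Without the filter H358T had 2345 lower and H1299 3756 higher. At 1.5-fold there were 5332 higher and 3926 lower in H358T, 6836 and 4953 in H1299, and 7119 and 4802 in H1703. In all 3 lines, 119 higher and 93 lower were left with normexp and 1262 and 801 were found at 1.5-fold; with each line left out, 481 to 743 were higher and 343 to 589 lower in both of the others, since fewer lines had to pass. The overlap over that of independent lists, higher and then lower, was 18.1 and 17.1 with normexp for H358T and H1299, 11.9 and 26.6 for H358T and H1703, and 12.2 and 25.2 for H1299 and H1703; without the filter it was 3.91 and 4.65, 3.92 and 4.94, and 3.90 and 6.84 in the same order. The correlation for H358T and H1299 was 0.47 with normexp, 0.38 with quantile normalization, 0.23 without the filter and 0.43 with signal on all 6 arrays. For H358T and H1703 it was 0.46 with normexp, 0.27 without the filter and 0.47 with signal on all 6 arrays, and for H1299 and H1703 it was 0.43 with quantile normalization, 0.30 without the filter and 0.42 with signal on all 6 arrays.

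Among named genes, ARHGDIA passed the threshold of 0.05 in limma with normexp (-0.91; adjusted p = 0.0441), quantile normalization (adjusted p = 0.0472), signal on all 6 arrays (adjusted p = 0.0358) and trend and robust settings (adjusted p = 0.0372), and not in the other fits. Its limma adjusted p of 0.0742 in the main fit is under the alternative threshold of 0.1. None of the genes that changed sign had passed a test. Quantile normalization gave -0.14 for RACK1, -0.22 for RPS18, -0.054 for RPLP1, -0.14 for COX4I1, -0.22 for ODC1, -0.18 for DYNLL1, -0.17 for ACTB, -0.026 for PGK1, -0.27 for ACTG1 and -0.32 for PFN1. With each line left out, PGK1 ran from -0.12 to 0.20, ODC1 from -0.012 to 0.27, RPL10 from -0.11 to 0.038 and PFN1 from -0.087 to 0.44. With array row as a term ODC1 was at -0.26 and PRMT1 at 0.053. Dim probes limit all counts: 19 of the higher calls were not above background on any NC siRNA array and 17 of the lower calls on any ETV4 siRNA array.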

Other observations

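The comparisons between cell lines and the test of neighbouring probes in this part were chosen only after the data were seen. More probes differed between the lines than the 614 that differed between the siRNAs. H358T alone carried the TGF-β treatment, so its differences from the other lines cannot be told apart from an effect of that treatment. In limma with the siRNA as the other term, 5391 probes were higher and 5573 lower in H358T than in H1299, 5596 higher and 6012 lower in H358T than in H1703, and 3841 higher and 3570 lower in H1299 than in H1703. Each line had 1 array per siRNA and no labelled repeat of a culture. The p-values for lines therefore rest on the spread of the siRNA difference between lines, and not on variation between cultures of a line. The arginine methyltransferase gene PRMT1 was higher in H358T than in H1299 by 1.33 on the log2 scale (limma adjusted p = 0.0143), and by 1.20 after quantile normalization. ODC1, which encodes ornithine decarboxylase, was lower in H358T than in H1703, with -1.34 (limma adjusted p = 0.00913) and -0.78 after quantile normalization. The histone gene H3-3A (-1.18; limma adjusted p = 0.0170) and the translation factor gene EIF3D (-1.10; limma adjusted p = 0.0384) were also lower in H358T than in H1703, with -0.55 and -0.38 after quantile normalization. RPL10 was lower in H1299 than in H1703, with -0.85 (limma adjusted p = 0.0400) and -0.89 after quantile normalization. Its probe had a signal of only 118 with NC siRNA, against 252934 for RPLP1. PRMT1 (-1.25; limma adjusted p = 0.0256), ARHGDIA (-1.01; 0.0277), H3-3A (-1.01; 0.0412) and ODC1 (-0.90; 0.0488) were also lower in H1299 than in H1703, but quantile normalization brought them to -0.45, -0.43, -0.16 and -0.22.

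In a principal component analysis of the 6 arrays, the first component (53.4% of the variance) parted H358T, the line treated with TGF-β, from the other lines. The second (29.6%) parted H1299 from H1703. The third (10.5%) parted the NC siRNA arrays (34.3 in H358T, 42.8 in H1299 and 70.2 in H1703) from the ETV4 siRNA arrays (-42.2, -43.8 and -61.4).

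A hypothesis was that probes with adjacent design identifiers report related transcripts and may change together. Across probes, the mean log2 differences of adjacent identifiers lying at least 500 µm apart on the array correlated at 0.07 (r = 0.0680), against 0.01 at an identifier gap of 1000, which is short of the gap of 0.1 set for the hypothesis. Among the 614 called probes, 36 had a called neighbour of the same sign within 2 identifiers, against a mean of 13.1 and a maximum of 34 in 1000 permutations. This count set no minimum distance on the array. The permutations did not match probes on signal, which also correlated between adjacent identifiers (r = 0.09).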
